A study of Homo sapiens with 2 samples.

How the data were processed

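Total RNA from 1 culture of HepG2 cells, a human liver cancer line, kept with the solvent dimethyl sulfoxide (DMSO) and from 1 culture kept with white tea extract (WTE) was measured, each on 1 Agilent array of 1 colour (Cy3). The group of each array was taken from the treatment label. Per the labels' treatment text the extract was given at 200 µg/mL for 24 hours, while the source name of the same sample says 100 µg/mL, so the dose is uncertain between these values. The control received DMSO at 1‰. Per the file headers both arrays sat on 1 slide, so the slide does not differ between the groups, and per the labels RNA integrity was good in both samples.

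The intensity values (processed, median and background brightness of each spot) and the spot flags were made with Agilent Feature Extraction 11.5.1.1 under the protocol GE1_1105_Oct12, per the file headers. The submitters' processing notes name version 10.7 of the same program. That program subtracts the background and raises spots that are not significant to a low positive value, per the file headers, and it does not scale arrays to each other. The authors also deposited a table of log2 values for the same arrays with no stated scale. Set against the scanner values, 98.8% of its DMSO and 99.0% of its WTE values lay within 0.001 of the log2 processed signal minus 1 constant per array, which puts the 75th percentile of its gene probes at 0.0099 and 0.0069. Its genes were not centred, and its columns have medians of -4.09 (DMSO) and -4.00 (WTE). How the authors chose the constants is not given in the sources used here.

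From the 58717 gene spots per array, the log2 processed signal minus the array's own 75th percentile was taken as the level. The 719 spots marked as non-uniform or as population outliers on either array were left out, and the spots of a probe were averaged. A probe counted as well above background on an array where at least 50% of its spots carried that mark. The files hold no gene symbols, so probes were named through their RefSeq accession, without its version, in a gene table of the assembly GRCh38.p14. Of 50599 gene probes, 28174 (55.7%) matched, to 20503 genes. The array annotation uses the build hg19, so no coordinates are given. A gene's level is the mean over its probes well above background on both arrays, which gave 15263 genes, 11287 of them from 1 probe. Where a gene was well above background on 1 array only, a bound was computed as the brighter level minus the higher of the dim probe's own level and the lowest level among spots well above background on the dim array. No spot was saturated.

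With 1 array per group there are no replicates, so no test was run, no p-value is given, and every difference describes these 2 arrays. Technical spread was taken from 707 probes spotted up to 10 times and from genes with several probes. Neither includes the spread between cultures. The number of arrays limits the precision. For each of 36 gene lists, fixed before the data were examined, the median log2 difference of the measured members was set among the medians of 10000 random lists of the same size, drawn from the same 10 classes of mean level. A list is said to stand apart where its median lay outside the central 95% of those medians. The members of a list are often regulated together, which random lists do not copy, so the percentile describes and does not test. Of 636 list entries, 17 genes stand in several lists, 21 symbols were updated and 2 could not be matched. Genes were named by a rule fixed at the same time. It takes, among genes with every probe well above background on both arrays, all probes in 1 direction, a brighter level at or above the median of -0.31 and a proper symbol, the 15 highest and 15 lowest log2 differences. It adds the 5 highest bounds each way and the 2 highest and 2 lowest members of each list. Some members that the rule takes are not reported here.

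The steps were tested on simulated arrays made from the DMSO spots with 200 genes of known difference. For WTE minus DMSO, over 15456 simulated genes, all 50 genes (100%) made 2 log2 units lower and all 50 made 2 log2 units higher were found past 2-fold. Of those made 1.5 log2 units lower or higher, 94% and 92% were found. Of 15236 genes with no difference, 38 passed 2-fold. Of 200 lists of unaltered genes, 10 stood apart (5%), and a list shifted by 0.5 had a percentile of 100. The simulation held only assumed noise of probes and spots and a constant shift, without spread between cultures or a trend with level. The 38 therefore follow from the assumed noise and do not estimate false calls in the real data. Lists drawn at random give about 5% by design.

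Alternatives were quantile normalization, scaling to the median of probes above background, an intensity-dependent loess fit (span 0.3), normexp background correction (offset 50), the authors' table, no filter on dim probes with a floor of 5, a signal of at least 100 on both arrays, the brightest probe per gene, outlier spots kept, a 1.5-fold threshold and random lists not matched on level. The normexp step used median spot signals, because the files used here hold no mean spot signals. Leaving out spots with an uneven local background and scaling to spike-in controls were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.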

Results

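The study compared the transcriptome of HepG2 cells, a human hepatocellular carcinoma line, after 24 hours with white tea extract (WTE) or with the solvent DMSO, to learn which functions of hepatic cells the extract affects. Each group had 1 array and no replicate, so the values below are differences between 2 arrays, without a test. The dose is given as 200 µg/mL in the treatment label and as 100 µg/mL in the source name. On the DMSO array 60.6% of the 58717 gene spots were well above background, and on the WTE array 62.5%. The 75th percentile of the processed signal was 4020 on the DMSO array and 4560 on the WTE array. Levels are log2 signals relative to that percentile, and differences are WTE minus DMSO.

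Of 15263 genes well above background on both arrays, 414 were at least 2-fold higher and 137 at least 2-fold lower on the WTE array, and 13252 (86.8%) lay within 1.5-fold. Differences of at least 4-fold were found for 66 genes in the higher and 7 genes in the lower direction. Spots of the same probe gave a log2 difference with an SD of 0.07, from 0.05 among probes of middle level to 0.11 among the dimmest, and 0 of 54866 pairs of such spots on an array were 2-fold apart. These values leave out spots flagged as outliers, and with them kept 42 of 63196 pairs were 2-fold apart. Different probes of a gene differed more, with an SD of 0.27. In all 70 genes past 2-fold with several probes each probe had the same direction. These 70 were picked on the mean of those same probes, which by itself makes agreement likely. The other genes past 2-fold rest on 1 probe. These spreads are technical and leave out the spread between cultures. The split between directions depended on the scale: 75.1% of the genes past 2-fold were on the higher side, and 40.6% (245 higher and 358 lower) when the arrays were scaled to spike-in controls, which shifted all genes by -0.23.

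**Figure D1:**
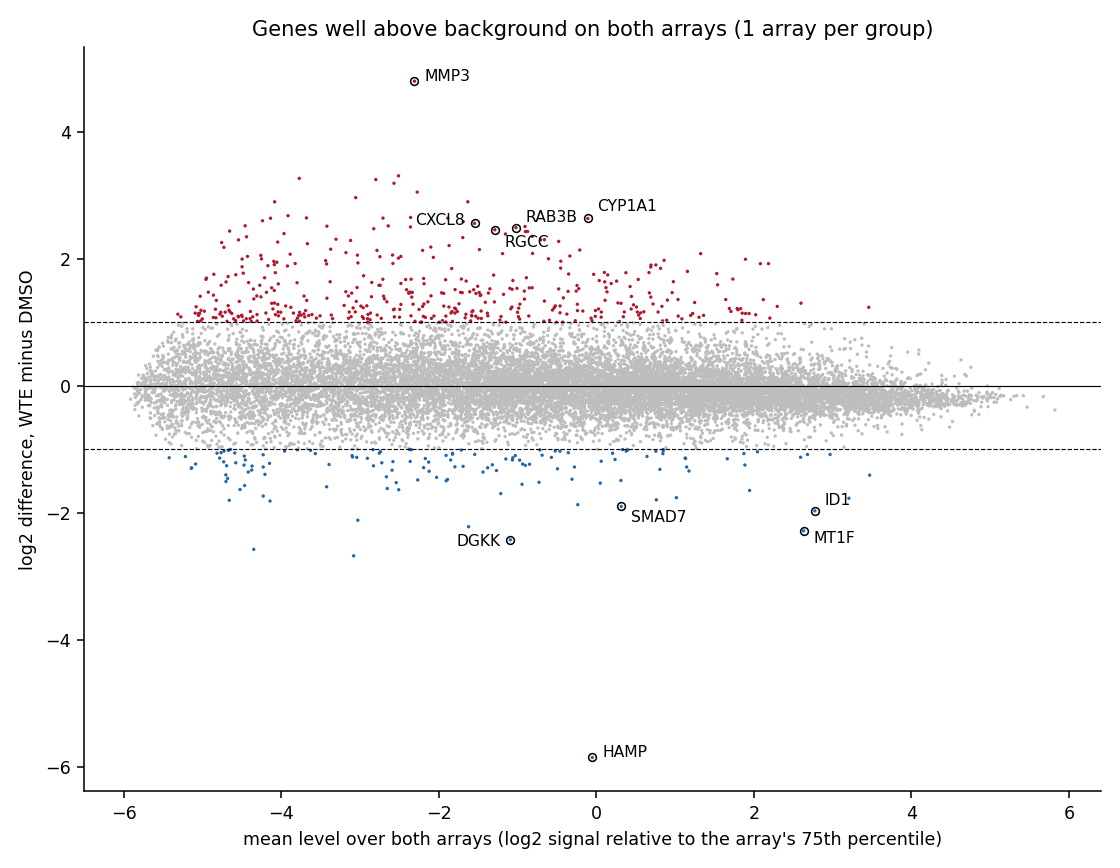
Log2 difference (WTE minus DMSO) of each gene well above background on both arrays against its mean level, in log2 signal relative to the array's 75th percentile, with 1 array per group. Red points are the 414 genes at least 2-fold higher and blue points the 137 at least 2-fold lower on the WTE array, dashed lines mark 2-fold, and circles mark the 5 highest and 5 lowest of the named genes, from MMP3 at 4.80 to HAMP at -5.85.

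Among the brighter genes, the highest difference was that of MMP3 (NM_002422), the matrix metalloproteinase stromelysin-1, which was 27.8-fold higher on the WTE array (level -4.71 with DMSO and 0.09 with WTE). CYP1A1 (NM_000499), a cytochrome P450 that the aryl hydrocarbon receptor induces, was 6.21-fold higher (-1.43 and 1.21). The chemokine gene CXCL8, which encodes interleukin-8, was 5.88-fold higher, and EDN1, the gene of the vasoconstrictor peptide endothelin-1, 5.11-fold higher over 2 probes. RAB3B, RGCC, AGR2, ASB2, RBM24, SPAG4 and CD3D had log2 differences between 2.27 and 2.49. DUSP5, a phosphatase of the kinase ERK, was 4.40-fold higher, and P2RY8, the scaffold gene AKAP12 and ZG16B had log2 differences of 2.08, 2.08 and 2.04. The MMP3 difference was 4.02 with normexp background correction, and that of AKAP12 was 1.67 with its brightest probe.

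The lowest difference was that of HAMP (NM_021175), which encodes the iron-regulating hormone hepcidin. It was 57.8-fold lower on the WTE array, at a level of 2.87 with DMSO and -2.98 with WTE. ID1 (NM_002165) and SMAD7 (NM_005904), both known targets of SMAD signalling, were 3.92-fold and 3.73-fold lower. The metallothionein genes MT1F and MT1G were 4.87-fold and 3.41-fold lower, and the glutathione transferase genes GSTA2 and GSTA5 3.47-fold and 3.39-fold lower. Members of these families resemble each other closely, so a probe may also bind a related transcript. NR1H4 (NM_005123), the gene of the bile acid receptor FXR, was 3.66-fold lower, and CEBPA, a transcription factor of hepatocyte differentiation, 3.13-fold lower. DGKK, a diacylglycerol kinase gene, had a log2 difference of -2.43. PAQR8, HOXD1, GATA2, DKK4 and LCN15 lay between -1.55 and -1.47.

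**Figure D2:**
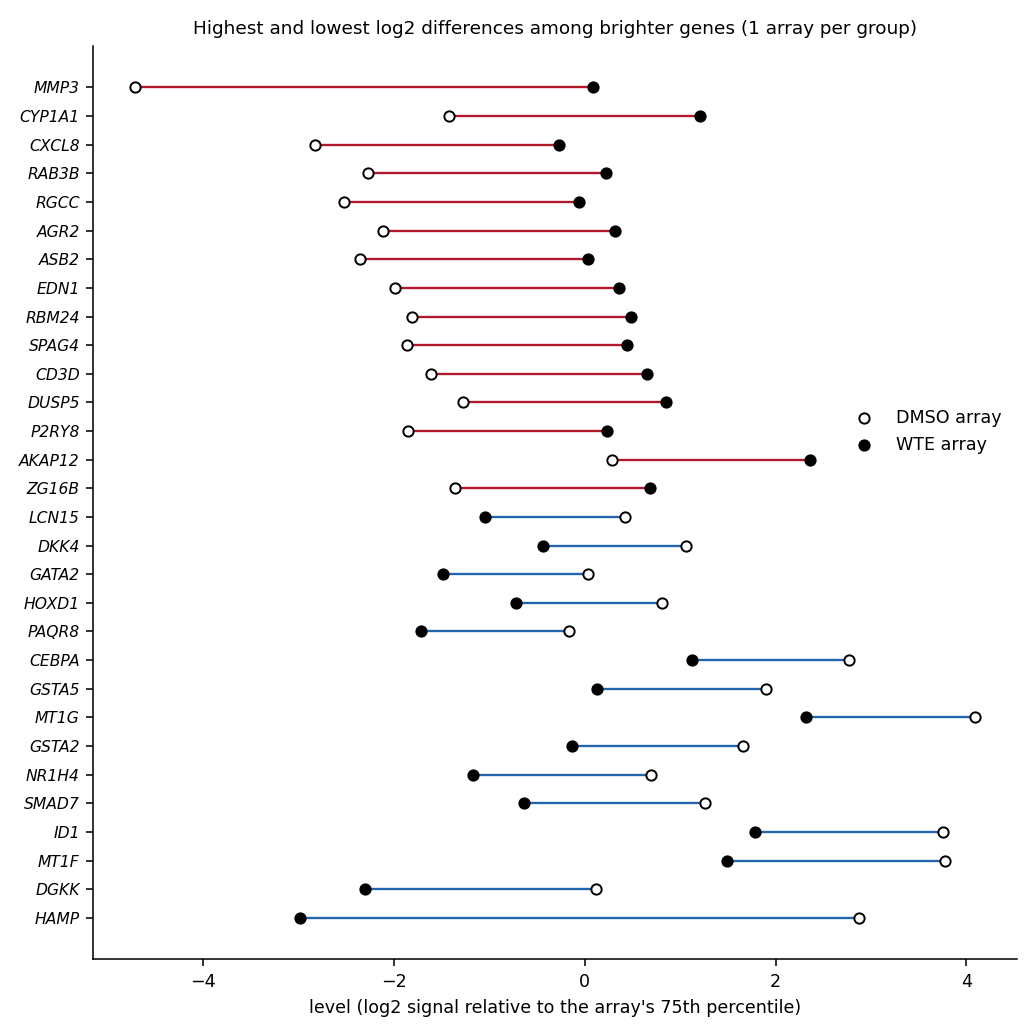
Levels of the 15 genes with the highest and the 15 with the lowest log2 differences among the brighter genes, in log2 signal relative to the array's 75th percentile. Open circles are the DMSO array, filled circles the WTE array, and line colour gives the direction (red higher, blue lower with WTE). HAMP goes from 2.87 to -2.98 and MMP3 from -4.71 to 0.09.

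Some genes were well above background on 1 array only, 496 on the WTE array and 178 on the DMSO array, and have bounds. MMP7, another matrix metalloproteinase gene, was at least 10.4-fold higher on the WTE array, and G6PC1, the gene of the glucose-releasing enzyme glucose-6-phosphatase, at least 8.79-fold higher. NKAIN1, LCK and HAVCR1 were at least 6.05-fold, 6.01-fold and 5.70-fold higher. In the other direction CCDC60 was at least 7.24-fold lower, PATL2 4.43-fold, IHH 4.42-fold, ACP3 3.67-fold and STMN4 3.56-fold. These bounds rest on dim spots, and with normexp correction all 10 were smaller, such as a log2 bound of 2.10 in place of 3.38 for MMP7.

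Of the 36 lists, 17 stood apart on the higher side and 4 on the lower side of the central 95% of random lists matched on level. For lists of genes drawn at random 1.8 in all would be expected. That number does not hold for lists whose members are regulated together, so the comparison describes and does not test. The lists of gluconeogenesis, cholesterol synthesis, hypoxia response and immediate early genes had medians of 0.81, 0.75, 0.59 and 0.51, and those of G2/M and mitosis and of G1/S and DNA replication -0.70 and -0.63. A list could stand apart with most members within 1.5-fold. This held for 17 of 19 autophagy, 14 of 16 glycolysis and 14 of 15 heat shock genes. It also held for 16 of 19 fatty acid oxidation, 18 of 23 amino acid response and 6 of 8 aryl hydrocarbon receptor genes.

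**Figure D3:**
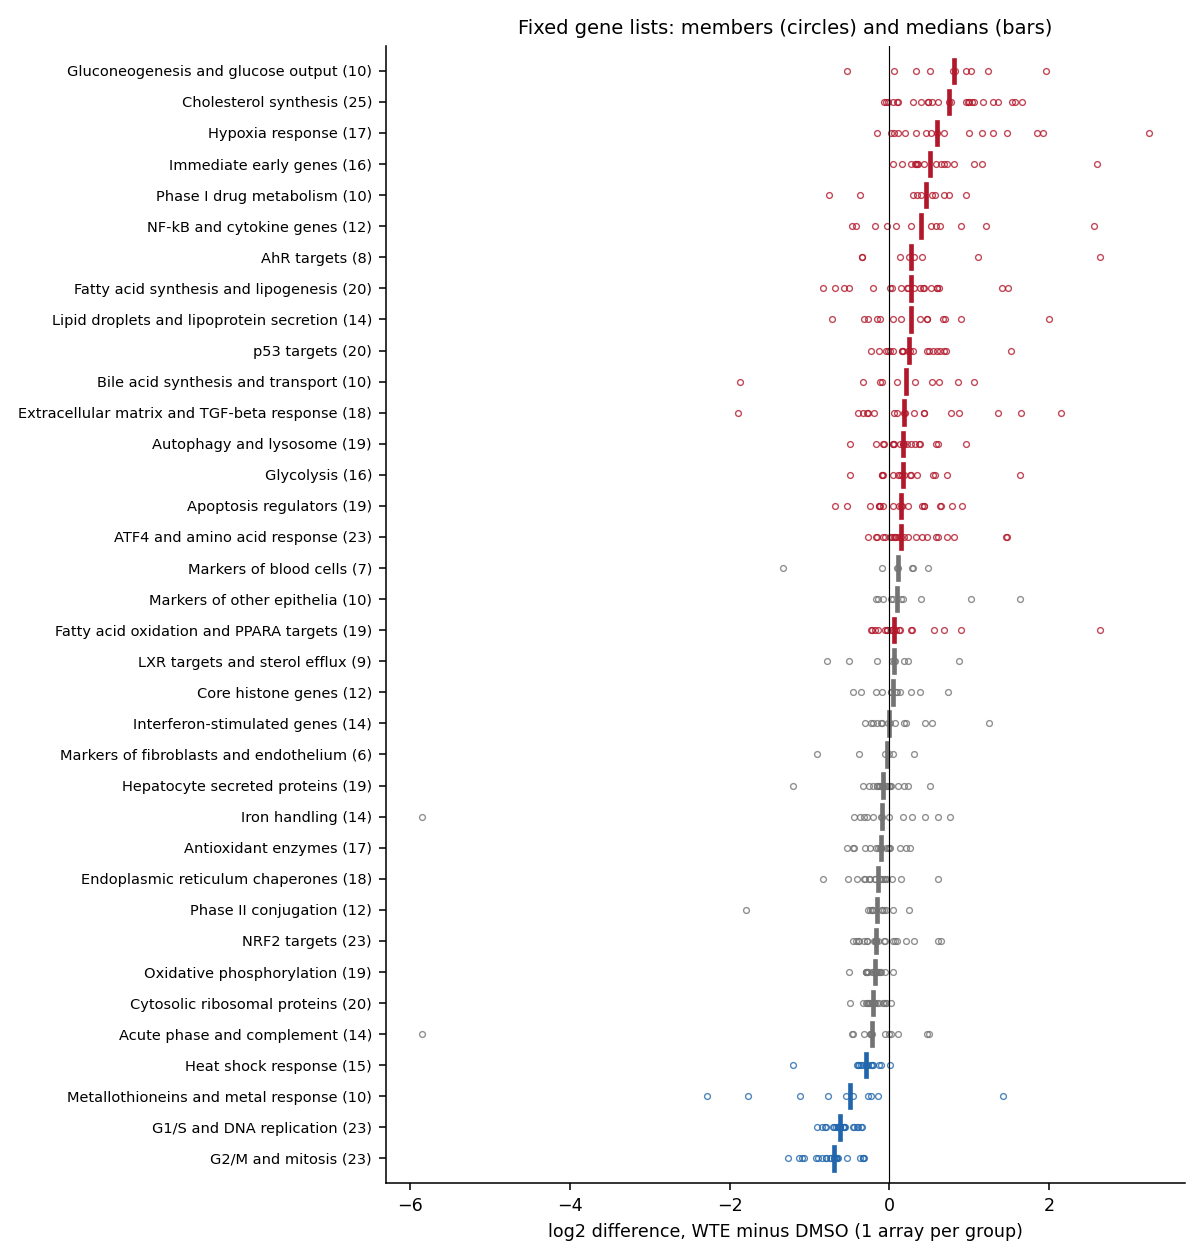
Log2 differences (WTE minus DMSO, 1 array per group) of the measured members of the 36 gene lists. Circles are genes, bars are list medians, the number measured is in parentheses, and colour marks lists above (red) or below (blue) the central 95% of matched random lists. Medians run from -0.70 for G2/M and mitosis to 0.81 for gluconeogenesis and glucose output.

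Genes of the cell cycle were lower on the WTE array. All 23 measured members of the G2/M and mitosis list lay below 0, 18 of them at least 1.5-fold, with a median of -0.70 (percentile 0). The proliferation marker MKI67 was at -1.27 and the mitotic kinesin KIF20A at -1.14, while HMMR and CDK1 were at -0.33 and -0.32. MKI67 was at -1.59 by its brightest probe. All 23 measured members of the G1/S and DNA replication list also lay below 0, 13 of them at least 1.5-fold, with a median of -0.63 (percentile 0). The helicase subunit MCM2 was at -0.91, the flap endonuclease FEN1 at -0.85, RRM1 at -0.36 and TYMS at -0.34. No alternative setting put a measured member of either list above 0. The list of p53 targets had a median of 0.25 (percentile 99.99), with 5 of 20 members at least 1.5-fold higher. Among them CDKN1A, the gene of the cell cycle inhibitor p21, was 2.88-fold higher and TP53INP1 was at 0.70, while FDXR and XPC were at -0.23 and -0.13. Core histone genes did not stand apart (median 0.05, percentile 91.7).

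Genes induced by low oxygen were higher as a list. In the hypoxia list 9 of 17 members were at least 1.5-fold and 7 at least 2-fold higher and 8 within 1.5-fold, with a median of 0.59 (percentile 100). CA9, carbonic anhydrase 9, was 9.49-fold higher from a low level of -4.42, and NDRG1 3.79-fold higher. CA9 was at 2.74 with normexp correction. VEGFA and EPO, also well-known targets of hypoxia-inducible factors, were at -0.16 and 0.02. Glycolysis genes had a median of 0.16 (percentile 99.98), with ALDOC 3.11-fold higher, HK2 at 0.72, PFKM at -0.49 and HK1 at -0.09. The median of this list was -0.064 when scaled to the spike-in controls, and HK2 was at 0.12 by its brightest probe. Gluconeogenesis genes had a median of 0.81 (percentile 100), with 6 of 10 members at least 1.5-fold higher. PCK1, which encodes the first committed enzyme of that pathway, was 3.89-fold higher, at a low level of -5.08 with DMSO, and IGFBP1 was 2.35-fold higher. With normexp correction PCK1 was at 1.33. SLC37A4 was at -0.54 and PCK2 at 0.06. Without spots of uneven background 5 members were left, with a median of 0.33.

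Cholesterol synthesis genes were higher as a group, with 14 of 25 members at least 1.5-fold and 8 at least 2-fold higher, none 1.5-fold lower, and a median of 0.75 (percentile 100). The sterol oxidase gene MSMO1 was 3.15-fold higher and the sterol sensor INSIG1 2.96-fold higher, while EBP and ACAT2 were at -0.07 and -0.05 and above 0 after quantile or loess normalization. In the lipogenesis list (median 0.27, percentile 100) members lay on both sides. ACSS2 was 2.79-fold and LPIN1 2.65-fold higher, and DGAT2 and GPAM, enzymes of triglyceride synthesis, were 1.77-fold and 1.61-fold lower. Its percentile was 94.0 without spots of uneven background. The lipid droplet list had a median of 0.27 (percentile 99.8). In it G0S2, an inhibitor of the triglyceride lipase ATGL, was 3.99-fold higher and the droplet coat gene PLIN2 1.86-fold, with PLIN5 at -0.72 and MTTP at -0.32. G0S2 had a low level of -5.25 with DMSO and was at 1.48 with normexp correction. Fatty acid oxidation genes had a median of 0.05 (percentile 98.3), with VNN1 6.23-fold higher and ACAA2 and ACOT1 at -0.23 and -0.22. VNN1 was at 2.33 with normexp correction. The median of this list was -0.17 when scaled to the spike-in controls and -0.00028 with median scaling. That list did not stand apart in 4 alternatives, with percentiles of 93.3 after loess, 92.7 after quantile normalization, 90.9 without spots of uneven background and 85.9 against unmatched lists. The LXR target list did not stand apart (median 0.05, percentile 85.0), with SMPDL3A at 0.87, SREBF1 at 0.23, MYLIP at -0.50 and ABCG8 at -0.78. SREBF1 was at -0.13 by its brightest probe and without spots of uneven background. Bile acid genes had a median of 0.21 (percentile 97.8), with SLC51A at 1.06, BAAT at 0.86, CYP27A1 at -0.33 and NR1H4 at -1.87. That median was -0.12 without a filter on dim probes and -0.022 when scaled to the spike-in controls. The list did not stand apart in 5 alternatives, with percentiles of 92.4 after quantile normalization, 94.2 after loess, 97.4 with normexp correction, 67.1 without a filter on dim probes and 97.2 against unmatched lists.

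Among genes of drug metabolism, the aryl hydrocarbon receptor list had a median of 0.27 (percentile 98.0). It did not stand apart in 4 alternatives, with percentiles of 95.8 after loess, 95.7 after quantile normalization, 95.0 without a filter on dim probes and 96.6 with the brightest probe. In this list CYP1A1 and ALDH3A1 were 6.21-fold and 2.16-fold higher, and NFE2L2 and SLC7A5 were both at -0.34. ALDH3A1 was at 0.52 by its brightest probe. Phase I genes had a median of 0.46 (percentile 99.9), with CYP3A5 at 0.96, CYP3A7 at 0.74, ADH4 at -0.37 and ALDH1A1 at -0.75, where the CYP3A genes are close paralogs. Phase II conjugation genes did not stand apart (median -0.15, percentile 40.5), and besides GSTA2 the members GSTO1 and UGT1A6 were at -0.27 and 0.24. Targets of NRF2, the regulator of antioxidant defence, did not stand apart either (median -0.17, percentile 23.5), with 21 of 23 members within 1.5-fold. TXNRD1 was at 0.64, SLC7A11 at 0.61 and UGDH at -0.42. All 17 measured antioxidant enzymes lay within 1.5-fold (median -0.11, percentile 82.0), from SELENBP1 at -0.53 and GPX2 at -0.45 to SOD2 at 0.20 and GLRX at 0.25.

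Metallothionein and metal response genes were lower as a list, with a median of -0.50 (percentile 0), 4 of 10 members at least 1.5-fold lower and 5 within 1.5-fold. SLC30A1 was at -0.14, and the zinc importer gene SLC39A10 went the other way with a 2.68-fold higher level. The percentile was 3.33 with the brightest probe per gene. In the iron list, HAMP alone was at least 2-fold lower, and the list did not stand apart (median -0.09, percentile 48.5). Ceruloplasmin (CP) was at 0.76, the iron exporter SLC40A1 at 0.60 and SLC11A2 at -0.44. Heat shock genes had a median of -0.29 (percentile 0.82), with CRYAB 2.30-fold lower, HSP90AA1 at -0.41, HSPA4L at -0.10 and HSPB1 at 0.01. Chaperones of the endoplasmic reticulum did not stand apart (median -0.15, percentile 39.9), with HSPA5 at -0.83, CRELD2 at -0.52, HERPUD1 at 0.15 and DNAJB9 at 0.61. The amino acid response list had a median of 0.14 (percentile 99.99), with PPP1R15A 2.76-fold and CHAC1 2.74-fold higher and PHGDH and SHMT2 at -0.26 and -0.16. Its median was -0.087 when scaled to the spike-in controls.

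All 16 measured immediate early genes lay above 0, with a median of 0.51 (percentile 100) and 7 at least 1.5-fold higher. EGR2 was 6.05-fold and FOSL2 2.23-fold higher, both from low levels, and NR4A1 and MYC were at 0.16 and 0.04 and below 0 when scaled to the spike-in controls. With normexp correction EGR2 was at 1.71 and FOSL2 at 0.49. The NF-kB and cytokine list had a median of 0.39 (percentile 99.9), with BIRC3 2.31-fold higher beside CXCL8, and NFKBIA and CXCL2 at -0.41 and -0.47. Without a filter on dim probes its median was 0.088 and its percentile 96.3. Matrix and TGF-beta response genes had a median of 0.18 (percentile 99.3, median -0.045 when scaled to the spike-in controls). In that list LAMB3 was 4.44-fold and CCN1 3.13-fold higher, COL4A2 was at -0.40 and SMAD7 at -1.90. LAMB3 had a low level of -4.45 with DMSO and was at 1.58 with normexp correction. Autophagy and lysosome genes had a median of 0.17 (percentile 100), with GABARAPL1 at 0.96, WIPI1 at 0.61, LAMP1 at -0.17 and TFEB at -0.50. By their brightest probes GABARAPL1 was at 0.60 and TFEB at -0.17. Apoptosis regulators had a median of 0.14 (percentile 98.8), with BCL2L1 at 0.90, APAF1 at 0.79, BIRC5 at -0.53 and BCL2L11 at -0.68. This list did not stand apart after quantile normalization (97.2), with the brightest probe (94.4) or against unmatched lists (97.3). The medians of the autophagy and apoptosis lists were -0.062 and -0.087 when scaled to the spike-in controls. Interferon-stimulated genes did not stand apart (median -0.0017, percentile 73.0), although OAS1 was 2.36-fold higher.

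Of the liver's secreted proteins, 18 of 19 measured genes lay within 1.5-fold (median -0.08, percentile 94.1), with FGA at 0.51, VTN at 0.24, APOH at -0.33 and HPX at -1.21. The acute phase and complement list did not stand apart (median -0.22, percentile 6.87), with SERPINA3 at 0.49, ITIH3 at 0.48, ITIH4 at -0.47 and HAMP at -5.85. Genes of oxidative phosphorylation (median -0.18, percentile 41.3) and ribosomal proteins (median -0.20, percentile 24.2) had all measured members within 1.5-fold. Markers of blood cells, of fibroblasts and endothelium and of other epithelia did not stand apart, with percentiles of 71.5, 42.5 and 85.0. Among them KRT14 was at 1.63 and SFTPC at 1.02, both from low levels, and CD14 and COL1A1 were at -1.33 and -0.91. With normexp correction KRT14 was at 0.91 and SFTPC at 0.70, and without a filter on dim probes KRT14 was at 0.46.

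Some small values given above changed sign with the setting. HERPUD1, SOD2 and PCK2 lay below 0 when scaled to the spike-in controls, and SHMT2 and LAMP1 lay above 0 after loess. EPO lay below 0 in 6 and HSPB1 in 5 alternatives, spike-in scaling among them, and MYC also with median scaling.

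The difference between the arrays depended on the level. The median difference was 0.02 in the dimmest of 10 equal classes of genes and -0.18 in the brightest. The 8 spike-in control probes well above background, which detect control RNAs that Agilent's labelling protocol adds to a sample, differed by -0.0032 to 0.40, with a median of 0.26.

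**Figure D4:**
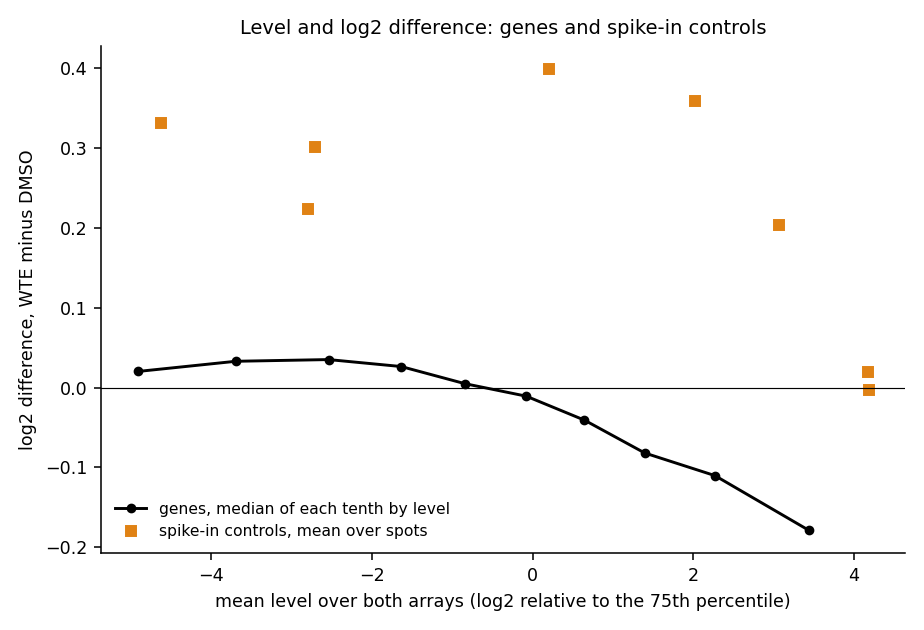
Median log2 difference (WTE minus DMSO) of genes in 10 equal classes of mean level, in log2 signal relative to the array's 75th percentile, and of 8 spike-in control probes, each the mean over 35 spots. Genes go from 0.02 in the dimmest to -0.18 in the brightest class, and the spike-in probes lie between -0.0032 and 0.40.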

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

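Scaling to the spike-in controls was chosen after the data were seen.

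Spike-in control probes are data that no comparison between genes uses, and they carried a difference between the arrays. After scaling, 7 of 8 probes well above background were higher on the WTE array, with a median of 0.26, while genes of like level had a median of -0.05. Before scaling all 8 were higher, by 0.18 to 0.58. The amounts of control RNA added are not given in the sources used here. All gene differences given here are relative to the other genes on the array. A step that set the arrays equal on these controls gave 245 genes at least 2-fold higher and 358 at least 2-fold lower.

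Probes that match no gene symbol here are also left out of the comparisons. Of 8154 such probes well above background on both arrays, 254 were at least 2-fold higher and 101 at least 2-fold lower on the WTE array.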

How the results depend on the processing

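Leaving out spots of uneven background and scaling to the spike-in controls were chosen after the data were seen. No paired analysis was possible because each group has 1 array. With no replicates, a value was taken as kept when it moved by less than 0.27, the SD between probes of a gene, a count within 1.5 times, and a percentile when it stayed inside or outside the central 95% as before. Median scaling and spike-in scaling shift all genes alike, by less than 0.27, so they cannot move a percentile or count as moving a gene, and the authors' values shift nearly all genes alike. In the settings other than these 3 1220 values of named genes kept and 29 moved, and 299 list percentiles kept and 22 moved. Of 288 list medians there, 276 kept their sign and moved by less than 0.27, 4 moved by more, and 8 changed sign, 7 of them in lists that did not stand apart. Settings that only choose probes or spots cannot change a gene that has 1 probe with 1 spot, only keep or drop it. Most named genes rest on 1 probe, so many of the 1220 kept values could not have moved. The floor of 5 moved nothing, since no signal lay below it. Of the 29 moved values 13 came from normexp, which also lowered all 10 bounds, and 9 from the brightest probe.

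Without a filter on dim probes 20495 genes were counted, in place of 15263, and 842 were higher and 397 lower. Of these, 398 and 132 were also past 2-fold in the main setting. The counts past 2-fold rose more steeply than the number of genes, and the added genes were not well above background on both arrays. At 1.5-fold 1175 were higher and 836 lower. Scaled to the spike-in controls 245 were higher and 358 lower, and the medians of 7 lists that stood apart turned negative, those of glycolysis (-0.064), fatty acid oxidation (-0.17), bile acids (-0.022), amino acid response (-0.087), apoptosis (-0.087), matrix (-0.045) and autophagy (-0.062), because all genes shift by -0.23. So did the medians of 4 lists that did not stand apart. The fatty acid oxidation median was -0.00028 with median scaling, which shifts all genes by -0.055. For the values that follow the cause was not tested. Without the dim filter the medians of bile acids and NF-kB were -0.12 and 0.088. Without uneven spots those of metallothioneins (4 genes left), gluconeogenesis and bile acids were -0.19, 0.33 and 0.53.

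Quantile normalization gave percentiles of 95.7 for the aryl hydrocarbon receptor list, 92.7 for fatty acid oxidation, 92.4 for bile acids, 97.2 for apoptosis and 98.0 for secreted proteins. Loess gave 95.8, 93.3 and 94.2 for the aryl hydrocarbon receptor, fatty acid oxidation and bile acid lists and 97.9 for secreted proteins. Normexp gave 97.4 for bile acids. Without the dim filter the percentiles were 95.0 for the aryl hydrocarbon receptor list, 67.1 for bile acids, 96.3 for NF-kB and 97.8 for other epithelia. The brightest probe gave 96.6 for the aryl hydrocarbon receptor list, 3.33 for metallothioneins and 94.4 for apoptosis. Without uneven spots lipogenesis was at 94.0 and fatty acid oxidation at 90.9. Unmatched random lists gave 85.9 for fatty acid oxidation, 97.2 for bile acids and 97.3 for apoptosis.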

Other observations

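The test against spot error was chosen after the result was seen. The patterns were noticed in these data and tested on other genes of the same arrays, listed before their values were looked at. Each stays a hypothesis, since a single culture per group leaves culture density, medium and handling untested.

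Further gene groups outside the fixed lists followed the same directions. Of 11 further BMP-SMAD target genes measured, 10 lay below 0, with SMAD9 at -1.29, ID4 at -1.28 and NOG at 0.53. Of 23 further hypoxia-induced genes, 18 lay above 0, with RORA and BNIP3L (1.21) the 2 past 2-fold and PFKFB3 at -0.26. All 31 further cell cycle genes lay below 0, from CLSPN at -1.43 to CKAP2L at -0.34. The groups were listed before their values were looked at, and only the members given as examples here were picked afterwards.

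HAMP, ID1, ID3, SMAD6 and SMAD7 were lower on the WTE array, with a median of -1.90, where ID3 (-1.41) and SMAD6 (-1.34) were picked after their values were seen. An intensity-dependent offset is argued against, since loess left a median of -1.83. With flagged spots kept, 2 of 7044 replicate spots lay as far from their probe's median as the smallest of the 5 lay from 0. Both were among the 2334 spots of dim probes, and the largest such distance was 1.85. This share is low for a spot taken without regard to its value. The 5 were picked by their values among 19720 probes with 1 spot, so the share cannot decide whether spot error lies behind them. Among dim probes, the share of probes with 1 spot that lay as far from 0 was 28.1 times that of replicate spots. That ratio also counts real differences between the arrays, so it cannot show what caused these 5. For any single gene of the 5, each measured by 1 spot, spot error stays open. Lower BMP-SMAD signalling in the treated culture is a candidate explanation, and the 11 further targets had a median of -0.57, at percentile 0 of matched random lists. Such targets are often regulated together, so these 11 extend the pattern and do not tell its causes apart. Whether the extract or another difference between the cultures lies behind the lower values was not tested.

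The hypoxia list was higher, and loess left its median at 0.64, which argues against an intensity-dependent offset. HIF activity in the treated culture may account for it, and 23 further hypoxia-induced genes had a median of 0.33, at percentile 100. Such genes are often regulated together, so these 23 extend the pattern and do not tell its causes apart. Of the 17 members of the hypoxia list 8 lay within 1.5-fold, among them VEGFA at -0.16, EPO at 0.02 and BNIP3 at 0.06. A denser culture with less oxygen could give the same values and was not tested.

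Both cell cycle lists were lower, with a joint median of -0.66 and of -0.57 after loess, which argues against an intensity-dependent offset. Fewer cycling cells in the treated culture may account for it, and 31 further cell cycle genes had a median of -0.62, at percentile 0. Such genes are often regulated together, so these 31 extend the pattern and do not tell its causes apart. Lower transcription of these genes in the same number of cycling cells would give like values and stays open.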
